A study of Mus musculus with 7 samples.

How the data were processed

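Polyadenylated RNA from mouse pancreatic spheroids was measured by RNA sequencing. Spheroids are 3-dimensional epithelial cultures, here grown from the pancreas of wild-type C57BL/6J mice. The mice were untreated or had earlier been given caerulein, a cholecystokinin analogue that causes acute pancreatitis. Groups and replicate numbers were taken from the sample titles and the treatment label, giving 3 untreated and 4 post-caerulein libraries. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be partly technical.

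The authors deposited raw counts of reads per gene, one column per library, with exon coordinates per gene, per the file headers. Reads were assigned to genes with featureCounts (version 0.6.1) on GRCm38, also named mm10, per the submitters' processing notes. The aligner and the strand setting are not given in the sources used here, so overlapping and antisense genes may share reads. The authors' deposited edgeR table gives log2 fold changes and average log2 CPM, the likelihood ratio score of each gene (LR) and its p-value and false discovery rate, per the file headers. Its edgeR version was 3.2.2, per the submitters' processing notes. Its filter and design are not given in the sources used here.

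The count table held 54446 genes, of which 54409 had a symbol. Total counts per library ranged from 34783738 to 46744497. At these depths 3 counts, the limit allowed by a count of 0, correspond to 0.0642 to 0.0862 CPM. Such limits and counting intervals (95%, exact binomial) cover counting error only. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), normalised by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, robust), two-sided, with Benjamini-Hochberg adjustment over the 16438 genes kept. An adjusted p under 0.05 was called. CPM values use TMM-scaled library sizes.

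A set of 34 gene lists with 903 members was fixed before the data were examined. All 903 members were matched, 3 of them under another symbol. Lists with at least 5 tested members, except the sex-linked genes, were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over 33 lists. Camera with an estimated correlation and fry were alternatives. Single values per library were compared by a two-sided exact permutation test over the 35 assignments of 7 libraries to 3 and 4, whose smallest p is 0.0286. Genes were named by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among called genes with non-overlapping groups and an average log2 CPM of at least 1, up to 4 members of each list, and 13 genes that are always given. Predicted and unnamed genes were counted, not named. A gene that the rule takes is not reported here. Called list members outside this rule (Cldn18, Muc4, Aqp5, Cebpd, Rsad2, Oas3, Fosl2, Ier3, Il33, Ankrd1, Prom1, Ambp and Hes1) were named after their values were seen.

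The design fixed in advance had the group as its only term. The authors' deposited table could not be obtained with that design: a likelihood ratio refit called 320 genes against 1023 in the table. Every split of the 7 libraries into 2 blocks was then searched. A block term holding untreated 03 and post-caerulein 04 (the smaller block, 2 libraries) against the other 5 (the larger block) gave back the table's log2 fold changes to within 3.2e-08 and all 1023 of its calls. No label states what the block stands for. The quasi-likelihood fit with this block was therefore added after the data were seen, and the rule for the largest changes was applied to it because the fit without the block called no gene.

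The procedure was tested on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold. For the comparison without the block, over 16048 genes, 37% of genes changed by 2-fold and 76% of those changed by 4-fold were recovered. For the comparison with the block, over 15802 genes, the shares were 65% and 92%. The simulated libraries were independent, without close pairs. Without the block they also shared the same baseline. Changed genes were not drawn from those of lowest expression. The shares may therefore not hold for the real libraries.

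Alternatives were other normalisations, no filter and a stricter filter (50 counts in 3 libraries), the replicate number as a block, each library left out, DESeq2 1.42.0, limma-voom, the quasi-likelihood test without robust estimation, a 0.01 threshold and a test against a fold of 1.5. The block of the deposited table, the larger block alone, a likelihood ratio test and summing of 2 close pairs of libraries were added later. Analyses ran in R 4.3.3 and figures were drawn with matplotlib 3.10.9.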

Results

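RNA was sequenced from pancreatic spheroids of 3 untreated and 4 post-caerulein libraries. The comparison asks what distinguishes epithelial cultures from a pancreas that had been through caerulein-induced inflammation from those of an untreated pancreas. Total counts were 41241985, 46260577 and 45966509 in untreated 01, 02 and 03, and 37824034, 34783738, 46524109 and 46744497 in post-caerulein 01 to 04. Krt19, a ductal keratin, was among the abundant transcripts in both groups, at 2708 ± 338.4 CPM (SD, n = 3) in untreated and 3117 ± 945.8 CPM (SD, n = 4) in post-caerulein libraries. Xist reached at most 0.0990 CPM in any library, while the Y-linked gene Ddx3y lay between 60.5 and 102.9 CPM in the 7 libraries.

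The libraries did not separate by group alone. The first principal component held 51.7% of the variance and set untreated 03 (70.4) and post-caerulein 04 (58.4) apart from untreated 01 (-67.7) and 02 (-63.4), with post-caerulein 01, 02 and 03 between them (-10.8, 8.06 and 5.03). Untreated 01 and 02 differed by a biological coefficient of variation of 8.44%, and post-caerulein 02 and 03 by 5.74%, against 21.9% or more for every other pair. Both close pairs differed by more than sampling noise, with chi-square values per gene of 13.3 and 10.3, which does not show that they are independent. Each library was counted separately, so the p values may rest in part on the small spread within these pairs. Fbln2, a fibulin of the extracellular matrix, was at 4000 CPM in untreated 03 and 3130 CPM in post-caerulein 04, against 381 to 931 CPM in the other 5. Egr1, an immediate early gene, was at 98.0 and 97.1 CPM in those 2 libraries and between 8.86 and 26.9 CPM in the rest.

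**Figure D1:**
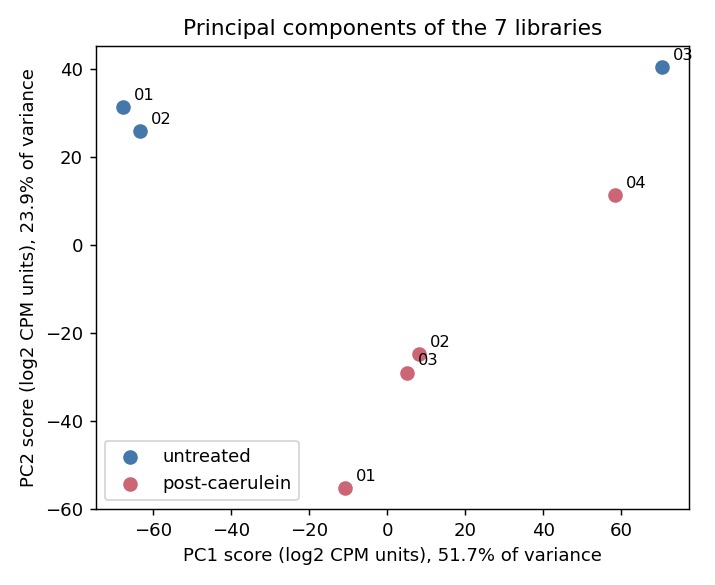
Scores of the 7 libraries on the first (51.7% of variance) and second (23.9%) principal components of log2 CPM, coloured by group and numbered by replicate. Untreated 03 (70.4) and post-caerulein 04 (58.4) lie at the right of the first component.

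Between the groups, Ccdc3, a secreted coiled-coil protein, stood at 7.93 ± 1.80 CPM (SD, n = 3) in untreated and 1.05 ± 0.263 CPM (SD, n = 4) in post-caerulein libraries. Tff3, a trefoil peptide of mucous epithelia, stood at 1.34 ± 0.199 and 89.6 ± 92.4 CPM, and St6galnac2, a sialyltransferase, at 1.69 ± 0.554 and 7.97 ± 0.577 CPM. None of these differences passed the test fixed in advance: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 16438 genes, with a smallest adjusted p of 0.0997, that of Ccdc3. At an unadjusted p under 0.05 there were 1561 genes, where chance gives 822. The groups did not overlap for 1532 genes, 9.32% of those tested, where chance gives 5.71%. Both chance values assume independent libraries. The close pairs each lie within a group, so neither excess shows a difference between the groups. DESeq2 called 509 genes and limma-voom 0. Without untreated 03 the quasi-likelihood test called 1149 genes (577 higher, 572 lower), and without post-caerulein 04 it called 57 (42 higher, 15 lower).

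With the block of the authors' deposited table as a term, which was added after the data were seen, 107 genes rose, among them Tff3, Ctrb1, Slco2a1 and the sialyltransferase genes St8sia6 and St6galnac2, and 144 fell, among them Ccdc3, Ihh and Bhlhe40. Tff3 (chromosome 17, 31125306 to 31129646, GRCm38) rose by 5.56 ± 0.97 (log2, SE; adjusted p = 0.0478, edgeR quasi-likelihood) and was higher in each of the 4 post-caerulein libraries, at 222, 41.2, 80.5 and 14.4 CPM, than in the untreated ones, at 1.16, 1.31 and 1.56 CPM. Ctrb1, an acinar chymotrypsinogen (chromosome 8, 111686519 to 111691010), rose by 5.60 ± 0.89 (adjusted p = 0.0378, edgeR quasi-likelihood) but from 0.105 ± 0.102 to only 4.42 ± 3.29 CPM. The sialyltransferases St8sia6 and St6galnac2 rose by 3.59 ± 0.43 and 2.29 ± 0.24. Slco2a1, a prostaglandin transporter, rose by 2.27 ± 0.26, from 26.2 ± 13.5 to 113 ± 29.3 CPM. The fit called 251 genes, 107 higher and 144 lower, and 156 of them had groups that did not overlap. It called 0 genes without untreated 01 or without untreated 02, 3 without post-caerulein 03, 29 without post-caerulein 02 and 131 without post-caerulein 01. Without untreated 03 it called 2267 and without post-caerulein 04 it called 2086. In these 2 settings the block term takes up the remaining library of the smaller block. Both therefore compare the groups in the larger block only, where a separate fit called 2247. With the counts of each close pair summed, the fit with the block called 0 genes.

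Other genes with large rises in that fit were Dcdc2a (3.98 ± 0.51, log2, SE), the trefoil gene Tff1 (3.37 ± 0.60), the Ras GTPase-activating protein gene Rasal1 (2.67 ± 0.41), BC025446 (2.13 ± 0.38), Lhfp (2.13 ± 0.33) and the PI3-kinase adaptor gene Pik3ap1 (1.86 ± 0.33). Among the 12 largest falls, Ccdc3 fell by 2.90 and Ihh, which encodes a hedgehog ligand (chromosome 1, 74945315 to 74951672), fell by 2.65, with SE of 0.28 and 0.30 and adjusted p of 0.0159 and 0.0226 by edgeR's quasi-likelihood test. Ihh stood at 22.5 ± 10.8 CPM (SD, n = 3) in untreated and 3.44 ± 1.03 CPM (SD, n = 4) in post-caerulein libraries. Dhrs3, a retinal reductase gene, fell by 2.57, the cation transporter gene Slc22a4 fell by 1.95, the connexin gene Gjb2 fell by 1.77 and the ephrin receptor gene Ephb3 fell by 1.60. Xlr3b fell by 1.59, Bmp4, a BMP ligand gene, fell by 1.56, the stress cytokine gene Gdf15 fell by 1.48, Col27a1 fell by 1.41, Grasp fell by 1.35 and the transcription factor gene Bhlhe40 fell by 1.28. Bhlhe40 was the most abundant of these, at 409 ± 47.4 CPM in untreated and 170 ± 43.8 CPM in post-caerulein libraries.

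**Figure D2:**
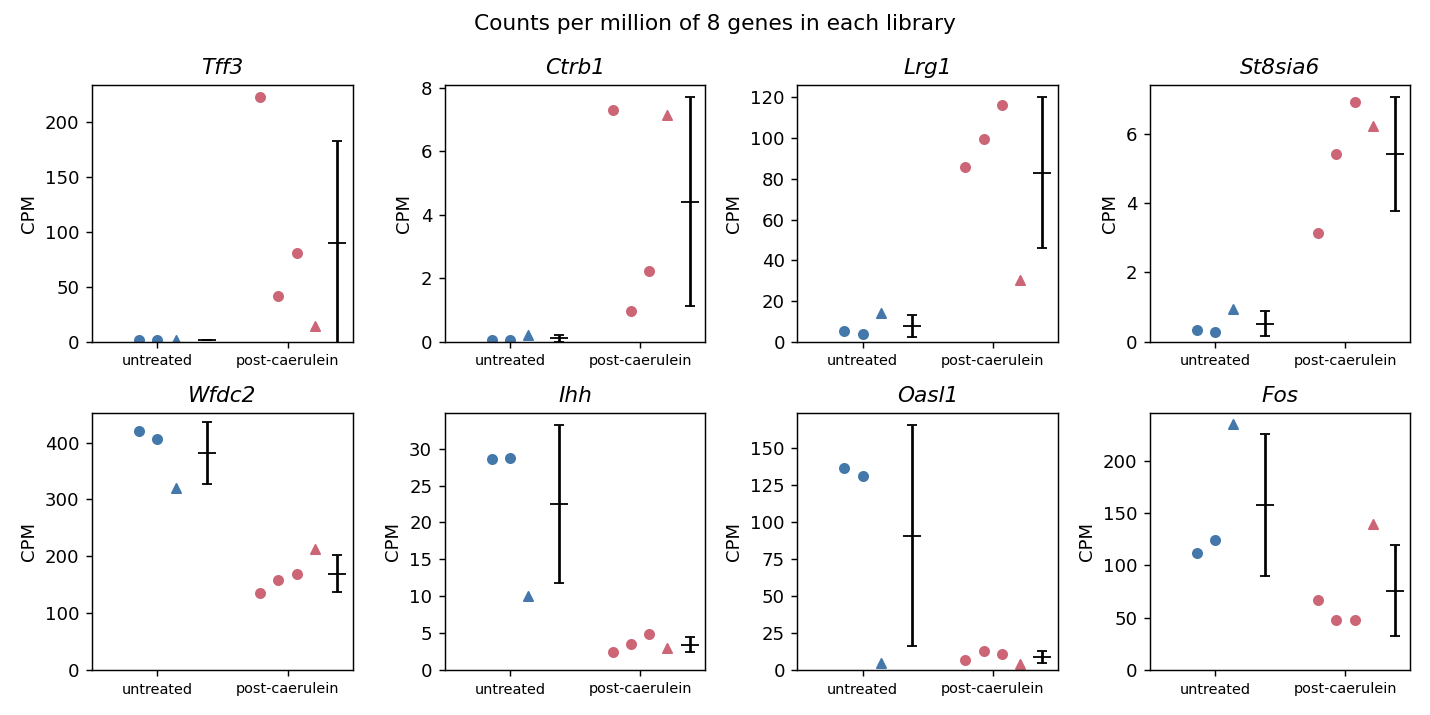
CPM of 8 genes in each library, with points for libraries, triangles for untreated 03 and post-caerulein 04, and bars for the mean and SD of each group (n = 3 and 4). Tff3 lies between 14.4 and 222 CPM in the post-caerulein libraries and at most at 1.56 CPM in the untreated ones, while for Oasl1 untreated 03 (4.56 CPM) lies with the post-caerulein libraries.

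Of the 33 gene lists tested, camera with the preset correlation of 0.01 called 11, 6 higher and 5 lower in post-caerulein libraries. With an estimated correlation it called 0, and fry called 0. Of the 35 splits of the 7 libraries into 3 and 4, the real one included, 17 gave at least 11 called lists, so the list calls below describe these libraries and were no more numerous than those of arbitrary groupings. No member of any list passed the test without the block over all genes. Below, counts of members that passed come from the fit with the block. Counts of members with positive or negative changes come from the fit without it, unless stated otherwise.

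The 6 lists called higher included gastric mucous and metaplasia genes, where 4 of 19 tested members rose and 2 fell with the block. Tff1, Tff2, Tff3 and the tight junction gene Cldn18 rose, Tff2 by 4.33 ± 0.64 (log2, SE), and the mucin gene Muc4 and the water channel gene Aqp5 fell. Camera gave the list an adjusted p of 0.00480, which was 0.308 with an estimated correlation and 0.426 without untreated 03. The list was not called with the block (0.0510) or in the larger block alone (0.308). Of 9 acinar genes 2 rose, Ctrb1 and the lipase gene Pnliprp2 (3.95 ± 0.47), and the list had an adjusted p of 0.00147 by camera and 0.308 with an estimated correlation. Cpa1 and Prss2, abundant products of acinar cells, were too low to test, with 1 read each in the untreated libraries and 58 and 90 reads in the post-caerulein ones. Their ratios were 46.2 (95% counting interval 7.97 to 1860) and 71.7 (12.5 to 2860), but 53 and 75 of those reads came from post-caerulein 04. Without that library the ratios were 5.57 (0.623 to 263) and 16.7 (2.57 to 704). Ptf1a, the acinar transcription factor gene, was at or under 0.0561 CPM in every library.

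Of 25 IL-6 and STAT3 response genes 3 rose and 1 fell with the block, and 9 and 3 did so adjusted over the list alone. The 3 that rose were Reg1, Reg3b and Reg3g, regenerating genes of the injured pancreas, and the transcription factor gene Cebpd fell by 1.12. Reg1 had 2 reads in the untreated and 359 in the post-caerulein libraries, a ratio of 143 (95% counting interval 39.3 to 1180), and Reg3b had 1 and 212, a ratio of 169 (30.0 to 6700). Lrg1, a secreted STAT3 target, was at 7.66 ± 5.51 and 83.0 ± 37.2 CPM, with an adjusted p of 0.0641 by edgeR's quasi-likelihood test with the block. The list had an adjusted p of 0.00147 by camera, 0.771 with an estimated correlation and 0.0581 without post-caerulein 01.

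Endocrine islet markers were called higher (adjusted p = 8.17e-05 by camera, 0.771 with an estimated correlation), with 0 of 8 members past the test over all genes and 6 higher adjusted over the list alone. Their levels were low: Chga, a granule protein gene, was at 0.112 ± 0.154 CPM in untreated and 1.38 ± 0.819 CPM in post-caerulein libraries, and Iapp had 2 and 105 reads, a ratio of 41.8 (95% counting interval 11.3 to 350). The call was lost without post-caerulein 01, 02 or 03 (adjusted p of 0.0982, 0.0676 and 0.166 by camera), and 5 of the 8 members were lower in post-caerulein 04 than in untreated 03. Fibroblast and stellate cell markers were called higher by camera (adjusted p = 0.00147, 0.771 with an estimated correlation, 0.104 without untreated 01, 0.0933 with close pairs summed), with a mean log2 change of 0.09 but a median of -0.17. Their median difference was 2.88 in the larger block and -0.95 between post-caerulein 04 and untreated 03. Col1a1, a fibrillar collagen gene, was at 8.70 CPM in untreated 03 and 0.0990 and 0.0422 CPM in untreated 01 and 02, against 1.33 to 3.28 CPM in post-caerulein libraries. Cholesterol and fatty acid synthesis genes were called higher (adjusted p = 0.00147 by camera, 0.771 with an estimated correlation), and 25 of 31 had a positive log2 change. Hmgcs1, of the mevalonate pathway, stood at 309 ± 21.3 and 480 ± 138 CPM, and the call was lost without untreated 03 (0.506) or post-caerulein 01 (0.0982) and in the larger block alone (0.268).

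Interferon-stimulated genes had a median log2 change of -1.10 over 40 members, 39 of them negative, and were called lower (adjusted p = 8.17e-05 by camera). With an estimated correlation of 0.891 the adjusted p was 0.771, and without untreated 01 it was 0.0675. With the block Rsad2 and Oas3 fell over all genes, the former by 2.50, and 33 were lower adjusted over the list alone. Oasl1, an antiviral gene, was at 137 and 131 CPM in untreated 01 and 02 but at 4.56 CPM in untreated 03, against 4.23 to 13.0 CPM in the post-caerulein libraries. Mx1 showed the same split, at 19.3 and 22.3 CPM in untreated 01 and 02 and 1.54 CPM in untreated 03. MHC and antigen presentation genes were called lower (adjusted p = 0.00435 by camera, 0.771 with an estimated correlation, 0.0932 with close pairs summed), and Tap1, a peptide transporter gene, fell by 0.54 with the block, from 96.7 ± 5.77 to 66.2 ± 5.12 CPM. B2m was at 558 ± 88.7 and 341 ± 66.2 CPM and did not pass.

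Of the other lists called lower, 2 of 26 p53 targets and senescence genes fell with the block, Gdf15 and Plk3, the latter by 0.72. The list had an adjusted p of 0.00435 by camera, 0.771 with an estimated correlation, 0.523 without untreated 03 and 0.268 in the larger block alone. Cytosolic ribosomal protein genes had 39 of 39 members negative but a median of -0.16 (adjusted p = 8.63e-06 by camera, 0.771 with an estimated correlation, 0.0780 without untreated 03). G2/M and mitosis genes were called lower (adjusted p = 0.00147 by camera, 0.771 with an estimated correlation). Their direction turned between the blocks, with a median log2 difference of -0.69 in the larger block and 0.76 between post-caerulein 04 and untreated 03, where 32 of 33 members were higher in post-caerulein 04. Ube2c, of the mitotic ubiquitin ligase, was at 92.4 ± 9.56 and 60.0 ± 11.99 CPM. The mitosis call was lost with close pairs summed (0.507) and without untreated 02 (0.0730), post-caerulein 02 (0.0899) or post-caerulein 03 (0.166).

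**Figure D3:**
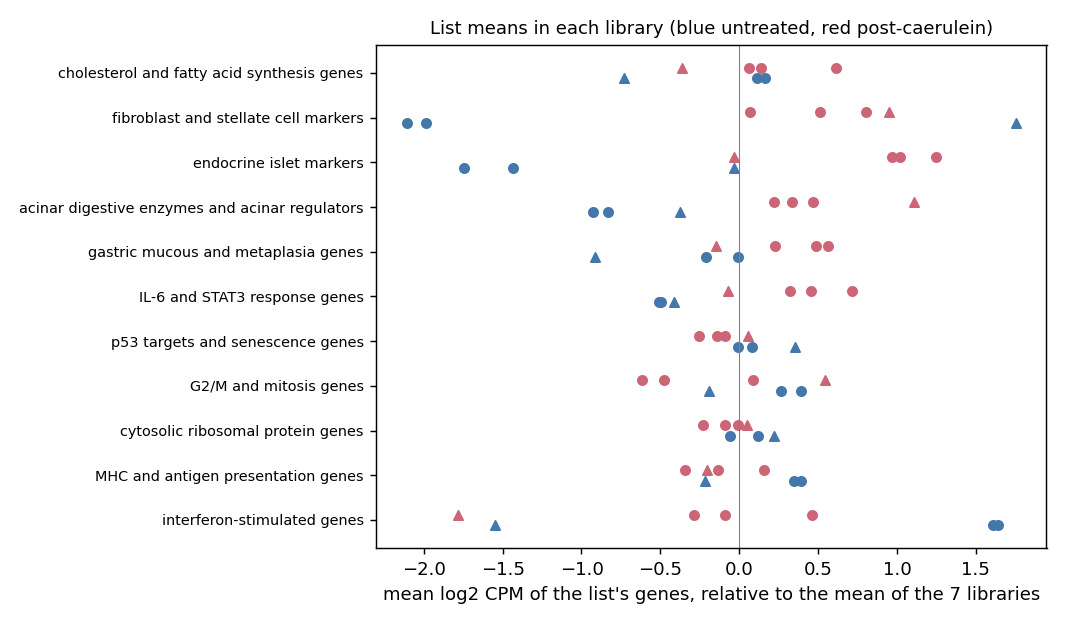
Mean log2 CPM of each of the 11 called lists in each library, relative to the mean of the 7 libraries, with blue for untreated, red for post-caerulein and triangles for untreated 03 and post-caerulein 04. The interferon-stimulated genes are highest in untreated 01 and 02, while untreated 03 lies with post-caerulein 04.

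The other 22 lists were not called by camera. Among signalling lists, MAPK, AP-1 and immediate early genes had an adjusted p of 0.0676. With the block 3 of its 37 members fell, Fos, Fosl2 and Ier3, while Dusp6, a MAPK phosphatase gene, was at 63.9 ± 10.5 and 32.2 ± 10.9 CPM (adjusted p = 0.0617, edgeR quasi-likelihood with the block). Junb was at 352 ± 85.0 and 233 ± 25.4 CPM, and Myc at 95.1 ± 95.8 and 147 ± 46.7 CPM, neither past the test. Il6 stayed at or under 0.124 CPM. Camera gave adjusted p of 0.278 for EGFR ligands and receptors, 0.222 for NF-kB targets and epithelial cytokines, 0.615 for TGF-beta and BMP response genes, 0.513 for Wnt and beta-catenin targets and 0.625 for YAP and TAZ targets. In the fit with the block Il33, an alarmin gene, fell by 1.29, the chemokine gene Ccl5 fell, Ankrd1 rose by 1.18, Wnt5a fell by 1.77 and Smad7, an inhibitor of TGF-beta signalling, fell by 0.91 with the block.

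Among identity lists, camera gave adjusted p of 0.504 for ductal epithelial genes, 0.132 for pancreatic progenitor and Notch genes, 0.443 for tuft cell genes, 0.222 for squamous and basal keratinocyte genes and 0.222 for EMT genes, whose median (-0.03) and mean (-0.12) were opposite in sign to camera's direction. With the block the EMT genes were called higher (adjusted p = 0.0197 by camera, 0.734 with an estimated correlation), with a median of 0.57, and they were called in the larger block alone (8.29e-05). Wfdc2, a ductal secretory gene, fell by 1.18 with the block, from 382 ± 54.7 to 169 ± 32.4 CPM, and Aldh1a1, a retinal dehydrogenase gene, rose by 0.89, from 116 ± 4.29 to 219 ± 48.2 CPM. Prom1 fell by 1.22, Ambp rose by 2.63, the Notch target gene Hes1 fell by 1.42 and the desmosomal gene Dsc2 fell by 0.81 with the block. Sox9, the ductal transcription factor gene, was at 28.5 ± 28.7 and 43.5 ± 6.61 CPM and did not pass. Krt13, a squamous keratin gene, fell by 5.54 with the block, but its untreated values were 36.6, 28.6 and 0.289 CPM. Basement membrane, integrin and adhesion genes had an adjusted p of 0.160. Markers of leukocytes (0.278), endothelium (0.983, mean of -0.33 against a median of 0.15) and Schwann cells and neurons (0.615, median of -0.20 against a mean of 0.18) were not called. Ptprc, the pan-leukocyte gene, reached at most 0.105 CPM.

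Among metabolic and stress lists, camera gave adjusted p of 0.312 for DNA replication and G1/S genes, 0.312 for hypoxia and glycolysis genes (median of 0.01 and mean of -0.05), 0.160 for unfolded protein response genes, 0.128 for NRF2, glutathione and detoxification genes, 0.870 for oxidative phosphorylation genes, 0.209 for mitochondrially encoded mRNAs and 0.222 for heat shock and dissociation stress genes. Cyp1a1, of xenobiotic metabolism, rose by 1.09 ± 0.20 (log2, SE) with the block.

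None of the 8 values per library differed between the groups by a two-sided exact permutation test. The smallest p was 0.0571 (adjusted 0.457), for the mean of the islet markers, at -1.57 ± 0.91 (log2 CPM, SD, n = 3) and 0.30 ± 0.57 (n = 4). Mitochondrially encoded genes took 2.22 ± 0.429% and 2.52 ± 0.202% of counts (exact p = 0.286), and the 50 most abundant genes 13.3 ± 1.14% and 13.6 ± 0.628% (exact p = 0.629).

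The authors' deposited table lists 12983 genes and 1023 with a false discovery rate under 0.05, 583 higher and 440 lower in post-caerulein libraries. In the authors' deposited table Tff3 has a log2 fold change of 5.62 and Ihh one of -2.63. Of the calls in the authors' deposited table, the quasi-likelihood fit without the block shared 0 and the fit with the block 208. Across genes, which are not independent replicates, Pearson's r between its log2 fold changes and the fits was 0.943 without and 0.998 with the block. The block was chosen to give back that table, so the values with the block are not independent agreement.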

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

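Tests of library size, swapped labels, fibroblast RNA and the effect of the block on interferon genes were chosen after the results were seen. Chance flags about 1 in 20 groups if the libraries are independent. Of 166 values examined in the 4 post-caerulein libraries, 25 had a library far from the other 3, where that rate gives 8.3. These libraries include a close pair, which by itself can make another library look distant. The genes and list means examined are not independent either, and some genes were chosen by their results. The excess over 8.3 therefore does not show more distant libraries than chance would give.

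In 18 of the 25 the distant library was post-caerulein 04. Its gap, as a share of the range of the 4, was 0.950 for Egr1, 0.908 for Xlr3b, 0.858 for Reg3g, 0.852 for Ephb3, 0.844 for Col6a3, 0.838 for Pcsk2, 0.831 for Iapp, 0.849 for Chga, 0.859 for Smad7, 0.836 for Hk1, 0.862 for Prom1, 0.901 for Cldn18, 0.938 for Aqp5, 0.901 for Muc4, 0.878 for Fosl2 and 0.851 for Il33. It was 0.956 for the mean of NRF2, glutathione and detoxification genes and 0.850 for squamous and basal keratinocyte genes. Post-caerulein 01 was distant for S100b (0.873), Ndufb8 (0.891), Rpl3 (0.865), mt-Nd2 (0.893), mt-Nd4 (0.867) and the Wnt and beta-catenin targets (0.935). Post-caerulein 03 was distant for leukocyte markers (0.878).

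Untreated 03 and post-caerulein 04 lay apart from the other 5 libraries, and they are the smaller block of the deposited table. Depth argues against library size: both, 2 of 2, had totals within 2% of a library on the other side (gaps of 0.640% and 0.471%), although in an earlier form of that test only 1 of the 2 totals lay inside the range of the other 5. Admixed fibroblasts would bring abundant collagen RNA, and the highest of Col1a1, Col1a2, Col3a1 and Dcn was 8.70 CPM in these 2 libraries. Swapped labels of the 2 stay open, since 51.9% (95% interval 49.8 to 54.0) of the genes called in the larger block had the same sign between the 2 libraries, neither reversed nor clearly shared. A batch, a different animal or a different culture behind the block may account for it, none of which the labels give, and no biological explanation was tested.

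Interferon-stimulated genes were lower on average in post-caerulein libraries. Their mean log2 CPM was highest in untreated 01 and 02 (4.95 and 4.92). Untreated 03 (1.76) lay below post-caerulein 01, 02 and 03 (3.02, 3.77 and 3.21) and above post-caerulein 04 (1.52). Leukocyte RNA is argued against, because Ptprc, Coro1a, Tyrobp, Laptm5 and Fcer1g together reached at most 0.322 CPM in untreated 01 and 02. The lower values did not need the 2 libraries that lay apart, but they rested on untreated 01 and 02. The median log2 difference was -1.37 in the larger block. Between post-caerulein 04 and untreated 03 it was -0.25, with 28 members lower and 12 higher. Whether the 2 libraries add to the pattern cannot be told. With the block the median log2 change was -1.11 and 40 of 40 members were negative, against -1.10 and 39 without it. Camera with the block gave an adjusted p of 3.33e-15, but 0.734 with an estimated correlation. The call was also lost with an estimated correlation without the block (0.771), so that loss does not bear on the 2 libraries. In the larger block alone 25 of 40 members were lower and 0 higher with adjusted p under 0.05 (edgeR quasi-likelihood), where the untreated side is 2 libraries that resemble each other closely. An effect of the earlier inflammation may be among the open explanations and was not tested separately.

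Camera with the preset correlation called acinar and islet genes, both at low level, higher in post-caerulein libraries. Neither list was called with an estimated correlation (adjusted p of 0.308 and 0.771 by camera). The mean log2 CPM of the islet markers was -0.53 in both untreated 03 and post-caerulein 04. Carry-over of acinar cells stays open. In 4 of 4 libraries 7 abundant acinar transcripts together lay below Ctrb1. Their reads were 20, 8, 5 and 213, against 261, 35, 106 and 340. Post-caerulein 04 came closest, with 38.5% (95% interval 34.4 to 42.7) of those reads from the 7 transcripts. Ctrb1 is itself an acinar enzyme gene, and its ratio to the 7 in acinar cells was not measured, so this cannot exclude carry-over. Pnliprp2, outside the 7, had 276 reads in post-caerulein 04 and 28, 17 and 28 in post-caerulein 01 to 03. Carry-over of islet cells also stays open. The 4 islet hormones lay below Iapp in 2 of 4 libraries, and none of the differences below it exceeded its counting interval. In post-caerulein 02 and 03 the hormones lay above Iapp. They held 65.3% (95% interval 53.1 to 76.1) and 64.9% (55.4 to 73.6) of the summed reads. Expression by the epithelial cells themselves may explain the acinar genes, as a hypothesis.

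Whether chance could give these counts was examined by other splits of the libraries. Without the block the real split called 0 genes, a count that every split must reach (35 of 35), so this comparison says nothing about chance. The highest other count was 48, for post-caerulein 01, 02 and 03 against the rest, which points to a structure of the samples. For gene lists 17 of 35 splits called as many as the real 11, the highest other calling 20, and chance cannot be excluded. With the block 1 of 20 splits within the blocks, the real one, called as many as 251 genes, and the highest other called 129. With 20 splits a share under 0.05 cannot be reached.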

How the results depend on the processing

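Results with the block, the larger block alone, the likelihood ratio test and the summed pairs were chosen after the data were seen; the other settings were fixed before. Without the block, 0 genes were called under the other normalisations, the stricter filter, limma-voom, non-robust estimation, the 0.01 threshold, the fold of 1.5, the summed pairs and the replicate block. The counts were 23 with no filter, 509 with DESeq2, 343 with the likelihood ratio test, 251 with the block and 2247 in the larger block alone. Leaving out each library gave 0 to 1149. Shared replicate numbers did not pair the libraries (correlations of deviations 0.372, 0.141 and -0.210), and the replicate block moved the list calls from 11 to 17. With the block, the 251 genes became 602 with no filter, 138 with the stricter filter, 1389 with DESeq2, 1227 with the likelihood ratio test, 9 at 0.01, 17 against a fold of 1.5 and 0 with close pairs summed, and 0 to 2267 with each library left out; limma-voom gave 358, of which 245 were shared. List calls were 8 to 17 without and 7 to 13 with the block when a library was left out, 7 with the stricter filter and block, and 0 with an estimated correlation or fry in both fits. Shared calls with the authors' deposited table were 0 without and 208 with the block. Col1a1 (log2 change -0.45) ranged from -1.02 to 4.94 with each library left out, reversed without untreated 03, and was 4.66 in the larger block alone. Mmp2 (-1.50) ranged from -2.09 to 3.10, likewise reversed, and was 2.51. Untreated 03 held the highest value of both; the cause of the other shifts was not tested. With a library left out the smallest exact p is 0.0667 or 0.100, so no value per library could pass. Genes near 3 counts per library are limited by depth.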

Other observations

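The analyses in this part were chosen after the data were seen. In the larger block alone, 2 untreated and 3 post-caerulein libraries, edgeR's quasi-likelihood test called 2247 genes, 1196 higher and 1051 lower. Nt5e, an ectonucleotidase gene, was at 110 and 87.7 CPM in untreated 01 and 02 and at 11.99 CPM in untreated 03, against 4.68 to 30.6 CPM in the post-caerulein libraries. Sox17, a transcription factor gene, followed the same course, at 139, 129 and 2.71 CPM in the untreated libraries and 2.40 to 15.0 CPM in the post-caerulein ones. Dsg3, a desmosomal cadherin gene, was at 53.2, 46.8 and 1.74 CPM, against 1.07 to 3.03 CPM.

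The difference between the groups itself differed between the blocks for 599 genes (interaction term, edgeR quasi-likelihood, adjusted p under 0.05), with 1 library per group in the smaller block. The spread in that test came from the larger block alone, where 4 of the 5 libraries form 2 close pairs, so the count may be too high; with the close pairs summed the fit with the block called 0 genes. Across genes, which are not independent replicates, the log2 differences of the 2 blocks had a Pearson's r of 0.0620. All 33 DNA replication and G1/S genes were higher in post-caerulein 04 than in untreated 03, with a median log2 difference of 1.06, while in the larger block their median was -0.28. The block term itself was called for 2724 genes.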
